A study of Bos taurus with 76 samples.

How the data were processed

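RNA from 38 bovine placentomes was hybridised to 76 oligonucleotide arrays with both channels read, 2 arrays per placentome with the Cy5 and Cy3 dyes exchanged, each time against a reference standard RNA whose composition is not given in the sources used here. Per the labels' protocols, RNA was isolated with Trizol, reverse-transcribed and coupled to the dyes, and the images were read with a GenePix scanner and its software. The deposited values are log2 ratios of Cy5 over Cy3 per spot, which the authors describe in the series record as adjusted to a normal distribution with no other normalization. The submitters' processing notes ask for the sign to be reversed where the sample was labelled with Cy3, and they name a mixed model in SAS with a false discovery rate as the authors' own test.

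From the deposited log2 ratios, the sign of each array with the sample in Cy3 was turned, so that positive values stand for more signal in the placentome than in the reference. Each array held 27648 spots, read as 13824 probes in neighbouring pairs, and the spots of a pair were averaged. Cells at the ceiling value (2522 cells at a log2 value of 16.61) and 40042 cells with no ratio were treated as missing. The median of each array was subtracted, because deposited array medians ran from −0.75 to 0.70, and the mean of the 2 arrays of a placentome was its value. All differences are therefore relative to the median probe of each array. A probe entered a comparison where both arrays gave a value in at least 50% of the placentomes of each group and in at least 2. The annotation gave 1 gene symbol for 8645 probes, several for 105 and no gene for 5074. These symbols stood for 8073 genes, of which 518 had more than 1 probe. By gene identifier, 8620 of the probes matched the RefSeq table and 0 symbols changed.

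One limma model (limma 3.58.1 in R 4.3.3) with a coefficient for each of the 9 groups was fitted to all 38 placentomes, with 29 residual degrees of freedom for a probe with no missing value, and 11 contrasts were tested with moderated statistics and Benjamini-Hochberg adjustment at 0.05 within each contrast. The adjusted p-values of single probes in all parts of the text come from limma. Gene lists (33, with 1320 entries of which 873 were on the array) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, over 7240 genes measured in every placentome, and 31 lists had enough genes for these tests. For a gene with several probes, the probe with the fewest missing values stood for the gene, and among ties the one whose dye orientations correlated most. Counts of list members refer to this probe, so a gene that passed with another probe was not counted. The comparisons, the thresholds, the gene lists and most of the alternatives were chosen before the data were examined. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

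Named genes followed a fixed rule. For each main comparison, the probes with 1 gene symbol that passed the threshold with the same sign in both dye orientations gave the 6 largest positive and the 6 largest negative differences, and the gene lists gave up to 2 genes each with the smallest p, up to 14 genes in all. The comparisons of NT hydrops and of other NT phenotypes with AI at term took 3 and 3 genes and no list genes. Where 5 or fewer probes passed, all were named, and where 0 passed, the 3 with the smallest p were named as not passing. XIST was always named. No probe for any of the 12 Y-linked genes looked for was found on the array. Other members of gene lists are named as examples of their list, and these were picked after their values were seen.

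Alternatives to the main processing were no centring of the arrays, scaling to the same median absolute deviation, quantile normalisation, a fit of single arrays with a dye term and the placentome as a random block, each dye orientation alone, a fit of the compared groups only, the sex of the calf as a covariate, IVF placentomes of 1 sex only, values from single arrays, a filter on probes whose 2 dye orientations correlated above 0.3 across placentomes, sample quality weights, and each placentome left out in turn. The fit and the list test were run on simulated placentome values with known differences. These values were drawn independently for each probe, so the processing of the arrays was not simulated. No sample was left out of the fit, but the IVF preterm placentome and the IVF term placentome of other phenotype were single samples and entered no contrast. The labels number placentomes as separate samples and give neither the cow, the donor cell line nor a hybridisation date. The p-values measure only the spread between these samples. For arrays there is no read depth, and the number of arrays limits the precision.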

Results

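Gene expression was measured in 38 placentomes, the sites in the cow's placenta where fetal cotyledon and maternal caruncle join. The pregnancies came from artificial insemination (AI), in vitro fertilisation (IVF) or somatic cell nuclear transfer (NT), that is cloning. At term there were 5 AI and 7 IVF placentomes of normal phenotype, 9 NT placentomes of normal phenotype, 3 NT placentomes with hydrops (excess fluid in the fetal membranes) and 5 NT placentomes of other phenotype. Preterm there were 4 AI placentomes and 3 NT placentomes with hydrops. Single IVF placentomes of normal phenotype (preterm) and of other phenotype (term) entered no comparison. All 20 NT calves were female and all 9 AI calves male, so every comparison of NT with AI also compared the sexes, and 2 of the 7 IVF calves were female. The array carried probes for 873 of the 1320 entries in the fixed gene lists.

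The 2 arrays of a placentome correlated with a Spearman coefficient between 0.28 and 0.63 across probes after the sign was turned, and the median was 0.48. Arrays of different placentomes with the same dye orientation correlated at a median of 0.66, and those with opposite orientation at 0.38. Between 0.12% and 9.58% of spots lacked a value on an array. The first principal component held 21.1% of the variance and set apart 5 placentomes with over 5% of spots missing on both arrays. These were NT normal placentomes 2 and 37, NT placentome 14 of other phenotype, AI preterm placentome 29 and AI term placentome 8856. The measured pregnancy-associated glycoproteins (PAG), a family made by the trophoblast, lay on average at −1.14 from their own group's mean in these 5 placentomes, and 0 of the 5 lay above their group's median. Against the same means, maternal caruncle and endometrium markers lay at 0.19 (5 of 5 above their group's median), endothelial markers at 0.22 (4 of 5), smooth muscle markers at −0.32 (0 of 5) and neutrophil and inflammatory genes at −0.18 (0 of 5). XIST, the RNA of the inactive X chromosome, stood at 4.68 ± 0.35 (SD, n = 4) in them and at 2.04 ± 1.51 (n = 33) in the others. XIST stood at 2.63 ± 1.01 (n = 22) with female calves and at 1.89 ± 2.26 (n = 15) with male calves, so it did not separate the labelled sexes, and the maternal part of a placentome is female in every sample. Its adjusted p was 0.702 or higher in the comparisons at term of NT normal, IVF and AI placentomes and 0.724 between AI term and preterm.

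**Figure D1:**
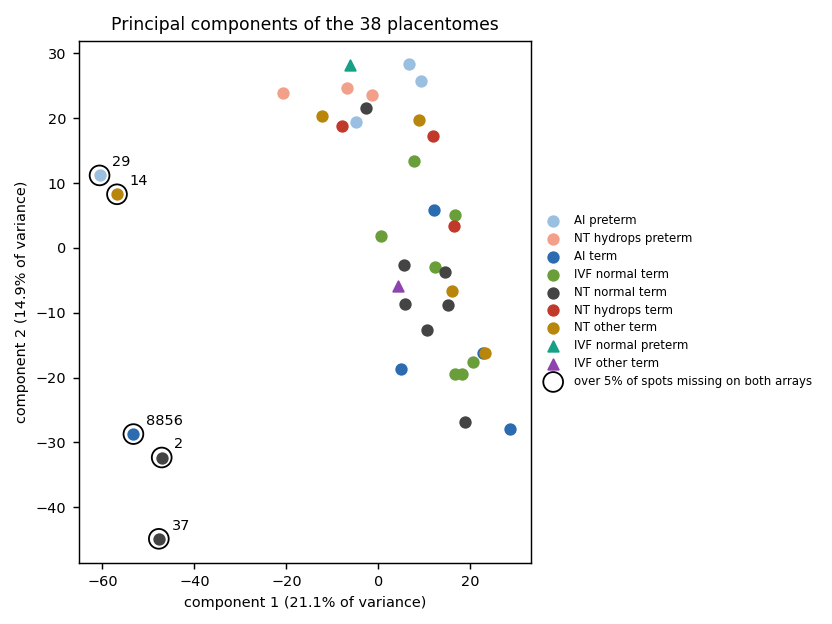
Position of the 38 placentomes on principal components 1 and 2 of the probes measured in all of them, with the percentage of variance on each axis, coloured by group. The 5 ringed placentomes, with over 5% of spots missing on both arrays, lie between −60.6 and −47.1 on component 1 and the nearest other placentome lies at −20.8.

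NT and AI placentomes of normal phenotype were compared at term, which asked how placentas of clones without a recorded abnormality differ from those after insemination. LAMA5, a laminin chain of basement membranes, stood at 1.39 ± 0.53 (SD, n = 9) in NT and at −0.07 ± 0.60 (n = 5) in AI placentomes, in log2 units of placentome over reference (log2 difference 1.45, SE 0.24, adjusted p = 0.0014), and all 9 NT placentomes lay above every AI placentome. MYOC, the secreted glycoprotein myocilin, stood at 1.38 ± 0.67 against −0.59 ± 0.46 (difference 1.97, SE 0.41, adjusted p = 0.00631), and GNA15, a G protein alpha subunit, at 1.46 ± 0.35 against −0.24 ± 0.77 (difference 1.70, SE 0.32, adjusted p = 0.00381), again with 9 of 9 NT placentomes above all AI placentomes. ECI2, which acts on unsaturated fatty acids in their oxidation, fell by 1.62 on the log2 scale (0.43 ± 0.43 against 2.05 ± 0.24, adjusted p = 0.00455). The peroxisomal oxidase ACOX2 rose by 1.45 (0.73 ± 0.37 against −0.72 ± 0.50, adjusted p = 0.00804), and the fatty acid synthase FASN rose by 0.92 (adjusted p = 0.0059). The kinase AKT2 (1.01), the cytokine LIF (0.87), the cyclin CCND3 (0.67), the histone H3 methyltransferase EHMT2 (0.73) and the basement membrane proteoglycan HSPG2 (0.70) rose, and the sodium, potassium and chloride cotransporter SLC12A2 fell by 1.19, with adjusted p-values from 0.00381 to 0.00876 and at least 8 of 9 NT placentomes beyond all AI placentomes. These 12 genes kept their calls whichever of the 14 placentomes was left out. Across placentomes the 2 dye orientations correlated at −0.18 for LIF, 0.13 for CCND3 and 0.23 for EHMT2, below the filter of 0.3. Their differences had the same sign in both orientations. The other probe of FASN and that of AKT2 had the same sign and did not pass.

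Other named genes lost their call in at least 1 of the 14 fits that each left out a placentome. CELA1 (−1.54), EGFL7 (0.94), NAP1L4 (0.73), IGF1R (0.58) and PARP14 (−1.10) lost it only without AI placentome 9674, with adjusted p-values of 0.1, 0.061, 0.055, 0.0804 and 0.0731. Another probe of NAP1L4 had the opposite sign. SPP1 (osteopontin, −1.81), NDUFA3 (0.78) and RPL23 (−1.06) lost it without AI placentome 9674 (adjusted p = 0.125, 0.0621 and 0.0902) and without AI placentome 1985 (0.0586, 0.0595 and 0.059). ANKRD1 (1.5) and ACKR4 (−1.98) lost it in 3 of 14 fits, ASZ1 (−1.65) in 4, FBLN2 (1.5) in 8 and MSTN (−1.97) in 9. For CELA1, EGFL7, IGF1R, NDUFA3, ACKR4, ASZ1 and MSTN the dye orientations correlated only between −0.13 (MSTN) and 0.18 (ACKR4) across placentomes. Among the lists, 5 of 56 measured cytosolic ribosomal proteins fell, 0 rose and 51 did not pass, and 6 fell when adjusted over the list alone. RPL23 fell by 1.06, RPS3A by 0.78, RPL35A by 0.88 and RPS29 by 0.61. The list lay lower as a whole (46 of 56 genes negative, median −0.19, camera adjusted p = 0.0032), with adjusted p = 0.892 with an estimated correlation, and its call was lost without AI placentome 1985 (adjusted p = 0.154). In the list of collagens and extracellular matrix, 4 of 54 genes rose (LAMA5, HSPG2, FBLN2 and COL6A2 by 0.93), 0 fell, and 4 rose when adjusted over the list alone, while the list itself did not pass (camera adjusted p = 0.412, and adjusted p = 0.892 with an estimated correlation). In the list of chromatin and DNA methylation regulators, 3 of 40 rose (EHMT2, EHMT1 by 0.47 and the Polycomb methyltransferase EZH2 by 0.59), 0 fell, and 4 rose when adjusted over the list alone. This list did not pass with camera (adjusted p = 0.183, and adjusted p = 0.892 with an estimated correlation). With fry its adjusted p was 0.0361. That test asks whether the genes of a list move 1 way on balance and does not set them against other genes. Results of fry are given in the text for this list only, so they do not set it apart from the other lists. Of the imprinted genes only NAP1L4 passed, 1 of 16 maternally expressed genes measured.

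Of 13737 probes tested in this comparison, 480 were higher and 274 lower in NT placentomes (limma), and 3053 had an unadjusted p under 0.05 where 687 would fall there by chance. Without centring the calls were 259 higher and 68 lower. With only the compared groups in the fit 70 probes passed, and with the sample in Cy3 alone 9 passed. With the calf's sex as a covariate 0 probes passed (limma, 1220 at an unadjusted p under 0.05). The calls ended because the SE rose. Over the 754 probes the median difference was 0.71 (median SE 0.33) with sex and 0.72 (0.18) without it, for example 1.4 (SE 0.43) for LAMA5 and 1.08 (SE 0.58) for ECI2 with sex. Leaving out 1 placentome gave 142 calls without AI 9674, 287 without AI 1039, 368 without AI 1985, 444 without AI 9026, 484 without NT 38 and 1855 without AI 8856.

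**Figure D2:**
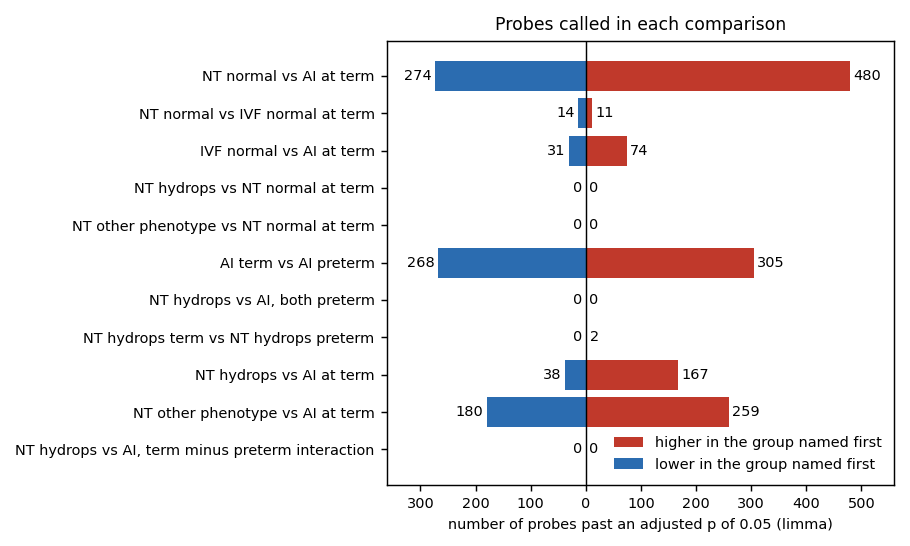
Number of probes past an adjusted p of 0.05 (limma) in each of the 11 comparisons, with those higher in the group named first to the right and those lower to the left. The longest bars are those of NT normal against AI at term (480 higher, 274 lower) and of AI term against AI preterm (305 higher, 268 lower), and 4 comparisons have 0 calls.

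NT and IVF placentomes of normal phenotype were compared at term, both groups having passed through embryo culture outside the cow. CCT2, a subunit of a chaperonin that folds cytoskeletal proteins, stood at −0.81 ± 0.38 (SD, n = 9) in NT and at 1.74 ± 0.75 (n = 7) in IVF placentomes (difference −2.55, SE 0.26, adjusted p = 3.42e-07), with no overlap. The splicing factor SLU7 stood at 1.08 ± 0.95 against 3.48 ± 0.67 (difference −2.40, SE 0.43, adjusted p = 0.00761), also with no overlap. PRP4, a prolactin-related protein of the ruminant placenta, stood at 6.47 ± 0.55 against 4.87 ± 0.53 (difference 1.60, SE 0.29, adjusted p = 0.00946), with 8 of 9 NT placentomes above all IVF placentomes. PAG17 stood at 5.15 ± 0.36 against 4.00 ± 0.33 (difference 1.15, SE 0.19, adjusted p = 0.0034), and its other probes had the same sign and did not pass. Members of the PAG and prolactin-related families are near-identical, so the identity of a single member behind a probe is uncertain. The spindle checkpoint gene MAD1L1 rose by 1.05 (adjusted p = 0.0127). The nuclear import receptor KPNA3 fell by 1.29, the epoxide hydrolase EPHX1 by 1.13 and the aldolase ALDOC by 1.0 (adjusted p = 0.0037, 0.00946 and 0.00959). These 8 genes kept their calls in all 16 fits that each left out a placentome. MCRIP1 (−1.23) lost its call in 2 of those fits, MDFIC (0.80) in 3, ANKS3 (0.94) in 4, AXL (0.76) in 8 and EVPL (−1.22) in 12. The dye orientations differed widely for AXL (1.42 with the sample in Cy5, 0.10 in Cy3) and for ANKS3 (0.21 and 1.67). Across placentomes they correlated at −0.34 for AXL and at 0.18 for ANKS3.

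Of 13742 probes tested between NT and IVF placentomes, 11 were higher and 14 lower in NT placentomes (limma), 1680 had an unadjusted p under 0.05, and without centring 44 were higher and 10 lower. The calls numbered 202 with the sample in Cy5 alone, 3 with it in Cy3 alone, 91 in the fit of single arrays with the placentome as a random block and 85 with only the compared groups. Of the 12 PAG genes measured, 0 passed over all probes with the probe taken for the list, while PAG17 passed with another probe, and PAG5 (1.11), PAG18 (0.98) and PAG17 (0.93 with that probe) passed when adjusted over the list alone. The PAG list did not pass as a whole (camera adjusted p = 0.0566, and adjusted p = 0.984 with an estimated correlation), and neither did any other list. Against the 2 female IVF placentomes alone 0 probes passed (limma, 738 at an unadjusted p under 0.05), where the differences were −1.85 for CCT2 (SE 0.34), −1.88 for SLU7 (0.67), 1.25 for PRP4 (0.46) and 1.04 for PAG17 (0.30). With sex as a covariate 0 passed (907), with a median over the 25 probes of 1.13 (SE 0.37), before 1.21 (0.25). Leaving out NT 37 gave 14 calls, IVF 12 gave 15, IVF 23 gave 16 and NT 21 gave 39.

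IVF and AI placentomes of normal phenotype were compared at term. CCT2 was higher in IVF than in AI placentomes too (1.74 ± 0.75, SD, n = 7, against −0.71 ± 0.46, n = 5), by 2.45 (SE 0.30, adjusted p = 2.93e-05). POLA2, a subunit of DNA polymerase alpha, rose by 2.75 (3.34 ± 0.31 against 0.58 ± 1.02, SE 0.52, adjusted p = 0.00719). LAMA5 stood at 1.60 ± 0.27 against −0.07 ± 0.60 (difference 1.67, SE 0.25, adjusted p = 0.000819) and ALDOC at 0.44 ± 0.26 against −0.93 ± 0.52 (difference 1.38, adjusted p = 0.00129). PRP4 fell by 1.89 (4.87 ± 0.53 against 6.76 ± 0.52, SE 0.34, adjusted p = 0.00514) and PAG7 fell by 2.31 (4.77 ± 0.40 against 7.07 ± 0.75, SE 0.42, adjusted p = 0.00517), although another PAG7 probe had the opposite sign. ECI2 fell by 1.69 (0.37 ± 0.50 against 2.05 ± 0.24, adjusted p = 0.00947) and FAM98A rose by 2.42 (adjusted p = 0.00947). All 7 IVF placentomes lay beyond every AI placentome in CCT2, POLA2, LAMA5, ALDOC, PRP4, PAG7 and ECI2, and these genes and FAM98A kept their calls in all 12 fits that each left out a placentome. SLU7 (2.32) lost its call without IVF placentome 27 (adjusted p = 0.0501) and FCGR3A (−1.22) without AI placentome 9674 (0.053). CNOT7 (1.92) lost it in 6 of 12 fits, SNCAIP (2.37), PAG5 (−1.32) and S100A4 (1.36) in 8, PAG18 (−1.33) and PAG17 (−0.91) in 9, SPINT1 (−1.64) in 10 and FBLN2 (1.81) in all 12. Over all alternatives PAG18 ran from −1.90 to −0.44, PAG17 from −1.06 to −0.42 and PAG5 from −1.98 to −0.63. Across placentomes the dye orientations correlated at 0.26 for PAG7 and 0.28 for SPINT1, below the filter of 0.3.

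**Figure D3:**
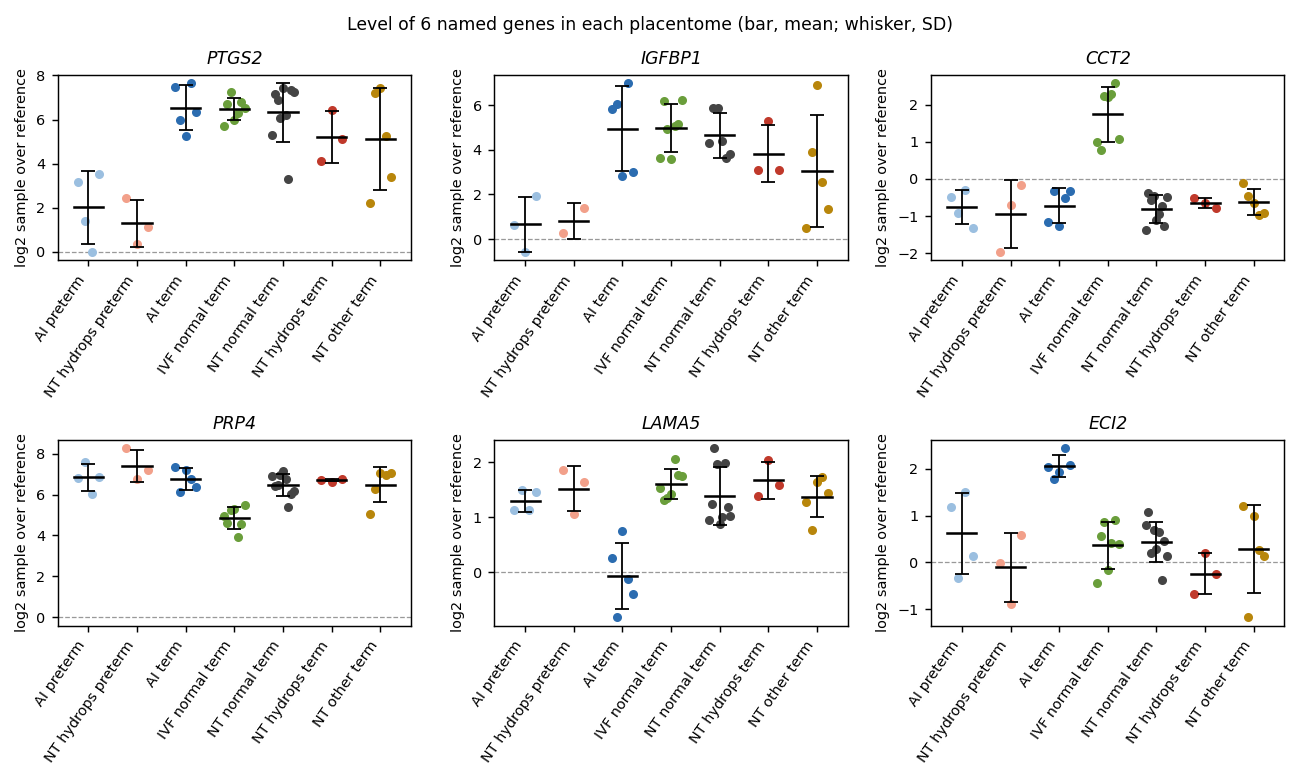
Level of 6 named genes in each placentome of the 7 groups compared, as log2 of placentome over reference after centring, with a bar at the group mean and whiskers of 1 SD. CCT2 lies above 0 only in IVF placentomes, PTGS2 stands at 2.02 in AI preterm and at 6.53 in AI term placentomes, and LAMA5 stands at −0.07 in AI term placentomes.

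The PAG list lay lower in IVF than in AI placentomes (2 of 11 measured genes positive, median −0.90, camera adjusted p = 0.000314), with adjusted p = 0.862 with an estimated correlation. Over all probes, and with the probe taken for the list, 2 of the 11 fell (PAG18 and PAG5), 0 rose and 9 did not pass, while PAG7 and PAG17 fell with another probe. Of the probes taken for the list, 4 fell when adjusted over the list alone, among them PAG4 (−1.22) and PAG2 (−1.45). The list did not pass after scaling to the same median absolute deviation (adjusted p = 0.738) or after quantile normalisation (adjusted p = 0.894). Its median ran from −1.03 to −0.04 over the 3 scalings. Among the prolactin-related genes, PRP4 was 1 of 6 to pass, and PRP1 (−0.86) was among 3 that fell when adjusted over the list alone. Of 13722 probes, 74 were higher and 31 lower in IVF placentomes (limma), 1917 had an unadjusted p under 0.05, and without centring 32 were higher and 32 lower. With the 5 male IVF placentomes alone 41 probes passed. The calls were 15 with the sample in Cy5 alone, 13 with it in Cy3 alone and 201 with only the compared groups. Leaving out a placentome gave 41 calls without AI 9674, 56 without AI 1039, 63 without AI 1985, 210 without AI 8856, 69 without IVF 7, 58 without IVF 23, 46 without IVF 26, 42 without IVF 27 and 59 without IVF 36.

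AI placentomes at term were compared with those of preterm AI pregnancies, which sets term against preterm without cloning. The samples are separate placentomes, so a difference need not reflect the advance of pregnancy and can come from other features of the groups. PTGS2 (cyclooxygenase-2, which makes prostaglandins) stood at 6.53 ± 1.01 (SD, n = 5) at term and at 2.02 ± 1.64 (n = 4) preterm (difference 4.51, SE 0.86, adjusted p = 0.00733), and CR2, a complement receptor, at 4.71 ± 1.23 (n = 4) against 0.16 ± 1.11 (n = 2) (difference 4.54, SE 0.82, adjusted p = 0.00824). Another probe of each passed too. The oxytocin receptor OXTR rose by 1.79 (2.21 ± 0.88 against 0.42 ± 0.44, adjusted p = 0.0116), with 4 of 5 term placentomes above all preterm ones. PDK4, which restrains pyruvate oxidation, rose by 3.10 (2.78 ± 1.42 against −0.32 ± 0.67, adjusted p = 0.0104) and podoplanin (PDPN) rose by 2.81 (adjusted p = 0.00824). The lysosomal protease CTSB (1.45), SULT1A1 (1.64), MCL1 (1.28), CLIC4 (1.42) and CEBPD (1.36) rose as well, with adjusted p-values from 0.00824 to 0.0128. The mitotic gene CDCA2 stood at −1.36 ± 0.67 against 0.74 ± 0.05 (difference −2.10, SE 0.51, adjusted p = 0.0187) and the fatty acid transporter SLC27A4 at 0.74 ± 0.27 against 2.53 ± 0.19 (difference −1.80, adjusted p = 0.0107). HMGA1 (−1.26), THY1 (−1.35), LAMA5 (−1.37), the replication licensing gene CDC6 (−1.08) and EHMT1 (−0.64) fell, with adjusted p-values from 0.00762 to 0.0136. These genes kept their calls in all 9 fits that each left out a placentome, except that CR2, measured in 2 preterm placentomes, was tested in 7 of them and kept its call there. MMP7 (2.85) and LOC338050 (−2.59) lost theirs in 2 of 9 fits, PTHLH (−2.46) in 3, IGFBP1 (4.29) and KCNE2 (−2.20) in 4, and DLGAP5 (−2.30) and NASP (−2.27) in 5.

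Between AI term and preterm placentomes the cell cycle list lay lower at term (42 of 50 measured genes negative, median −0.44, camera adjusted p = 4.28e-05), with adjusted p = 0.486 with an estimated correlation. Of its 50 genes 5 fell, 0 rose and 45 did not pass, and 10 fell when adjusted over the list alone. UBE2C fell by 1.75, NUSAP1 by 1.60, CDC45 by 1.14 and MCM2 by 0.90. Of 40 chromatin and DNA methylation regulators, 5 fell and 0 rose (7 fell when adjusted over the list alone), among them SMARCB1 (−1.02), EHMT2 (−0.77) and EZH2 (−0.73), with a camera adjusted p of 0.00462, adjusted p = 0.346 with an estimated correlation, and 0.000736 with fry. Of 41 neutrophil and inflammatory genes, 3 rose and 0 fell (6 rose when adjusted over the list alone), which were CEBPD, TLR4 (1.52) and CXCL8 (0.89), with a camera adjusted p of 0.00201 and adjusted p = 0.486 with an estimated correlation. Of 28 angiogenesis genes 4 rose (CCN2 by 2.00, TGFB3 by 1.75, EPAS1 by 1.31 and JAG1 by 1.04), with a camera adjusted p of 0.0211 and adjusted p = 0.486 with an estimated correlation, and 8 rose and 2 fell when adjusted over the list alone. This call was lost without AI preterm 5 (adjusted p = 0.0702) or 29 (0.0724) and without AI term 8856 (0.0654) or 9026 (0.0516). Of 29 matrix metalloproteinases and inhibitors 2 rose, CTSB and MMP7 (camera adjusted p = 0.0138, and adjusted p = 0.513 with an estimated correlation), a call lost without AI preterm 29 (0.123). Of 27 interferon-stimulated genes 3 rose, IFI6 (1.74), PARP14 (1.28) and IFIT5 (0.92), with a camera adjusted p of 0.0305 and adjusted p = 0.513 with an estimated correlation. This call was lost without AI preterm 29 (0.123), AI term 8856 (0.0654) or AI term 9026 (0.0532). The endothelial list passed with 0 of 25 genes past the threshold (camera adjusted p = 0.0178, and adjusted p = 0.513 with an estimated correlation), and not without AI preterm 5 (0.117) or AI term 8856 (0.393). In the list of prostaglandin and parturition genes 3 of 28 rose (PTGS2, OXTR and PGRMC1 by 1.14), and 6 rose and 1 fell when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.182, and adjusted p = 0.513 with an estimated correlation).

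Of 13741 probes compared between AI term and preterm, 305 were higher and 268 lower at term (limma), 2745 had an unadjusted p under 0.05, and without centring 442 were higher and 83 lower. With both dye orientations apart, 122 probes passed with the sample in Cy5 and 229 with it in Cy3. With only the compared groups in the fit 90 passed. Leaving out a placentome gave 175 calls without AI term 9026, 215 without 1985, 333 without 1039 and 1158 without 8856, and 241 without AI preterm 33, 244 without 15, 296 without 5 and 319 without 29.

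NT placentomes with hydrops were compared with NT placentomes of normal phenotype at term, which set 3 placentomes against 9. No probe of 13749 passed (limma, 822 at an unadjusted p under 0.05, and 6 probes in the fit of single arrays with the placentome as a random block). PLA2G12A, a secreted phospholipase, stood at 1.69 ± 0.37 (SD, n = 3) in hydrops and at 0.27 ± 0.49 (n = 9) in normal placentomes, with 3 of 3 above all 9 (difference 1.42, SE 0.35, adjusted p = 0.801, not passing). CERT1 (1.69) and KLF11 (1.19) did not pass either (adjusted p = 0.801). With no single gene past the threshold over all probes, 7 lists passed by camera at the preset correlation, and 0 with an estimated correlation. Cytosolic ribosomal proteins lay higher in hydrops (51 of 56 genes positive, median 0.42, camera adjusted p = 2.05e-10, and adjusted p = 0.355 with an estimated correlation), for example RPS20 at 1.10 and RPL23 at 0.80. Cell cycle genes lay higher (40 of 50 positive, median 0.51, camera adjusted p = 2.73e-05, and adjusted p = 0.372 with an estimated correlation), for example UBE2C at 1.25 and CDK1 at 0.98. Oxidative phosphorylation genes lay higher (59 of 68 positive, median 0.22, camera adjusted p = 0.000105, and adjusted p = 0.372 with an estimated correlation), for example NDUFB6 at 1.03. PAG genes lay higher (12 of 12 positive, median 0.79, camera adjusted p = 0.00398, and adjusted p = 0.381 with an estimated correlation), but not after quantile normalisation (adjusted p = 0.276). Lower lay MHC class II genes (1 of 10 positive, median −0.32), leukocyte markers (13 of 47 positive, median −0.08), both with a camera adjusted p of 0.00516 and adjusted p = 0.355 with an estimated correlation, and endothelial markers (5 of 25 positive, median −0.16, camera adjusted p = 0.00398, and adjusted p = 0.381 with an estimated correlation), for example PECAM1 at −1.0. The list test itself held 32 of the leukocyte genes and 8 of the PAG genes. The NT normal group held 2 of the 5 placentomes with many missing spots and the hydrops group 0. Without these 5 the mean of the PAG list fell from 0.86 to 0.56 (adjusted p = 0.00264) and that of endothelial markers went from −0.19 to −0.10 (0.0486). The endothelial call was lost without hydrops placentome 31 (adjusted p = 0.0539) and after scaling to the same median absolute deviation (0.0507). In these 7 lists 0 members passed when adjusted over the list alone.

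NT placentomes of other phenotype were compared with NT placentomes of normal phenotype at term. No probe of 13732 passed (limma, 791 at an unadjusted p under 0.05, and 2 in the fit of single arrays with the placentome as a random block). CR2 stood at 1.66 ± 1.14 (SD, n = 4) against 3.74 ± 0.96 (n = 8) (difference −2.07, adjusted p = 0.401, not passing), and NPY2R, a neuropeptide Y receptor, at −2.12 ± 0.03 (n = 3) against 0.04 ± 0.68 (n = 8) (difference −2.17, adjusted p = 0.401, not passing). CRIPT (0.58) did not pass (adjusted p = 0.697), though 5 of 5 placentomes lay above all 9. Of the lists, 11 passed by camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.348, or 0.397 for collagens and extracellular matrix), and in these 11 lists 0 members passed, over all probes or adjusted over the list alone. Higher lay cytosolic ribosomal proteins (51 of 56 positive, median 0.26, camera adjusted p = 4.03e-07), PAG genes (12 of 12 positive, median 0.69, camera adjusted p = 0.00152), and cell cycle and oxidative phosphorylation genes (40 of 50 and 55 of 68 positive, camera adjusted p = 0.000157), whose medians turned below 0 under 1 of the scalings. Lower lay neutrophil and inflammatory genes (5 of 41 positive, camera adjusted p = 0.000534), matrix metalloproteinases (8 of 29, 0.00152), endothelial markers (6 of 25, 0.00155), collagens and extracellular matrix (15 of 53, 0.00155), smooth muscle markers (4 of 20, 0.00294), MHC class II (1 of 10, 0.0224) and leukocyte markers (14 of 46, 0.0296).

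The list calls of NT placentomes of other phenotype rested largely on NT placentome 14, 1 of the 5 with many missing spots, since only 3 lists passed without it. These were the ribosomal, PAG and oxidative phosphorylation lists. The adjusted p without it was 0.0783 for endothelial markers, 0.221 for MHC class II, 0.294 for cell cycle, 0.36 for smooth muscle, 0.532 for leukocyte markers and for neutrophil genes, 0.697 for metalloproteinases and 0.788 for extracellular matrix. The PAG call was lost without NT 19 (adjusted p = 0.211) and after scaling to the same median absolute deviation (0.418) or quantile normalisation (0.155). MHC class II was also lost without NT 2 (0.0975), 19 (0.102), 21 (0.0672), 28 (0.0506) or 32 (0.198), and leukocyte markers without NT 2 (0.122), 21 (0.101), 32 (0.163) or 46 (0.0776).

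**Figure D4:**
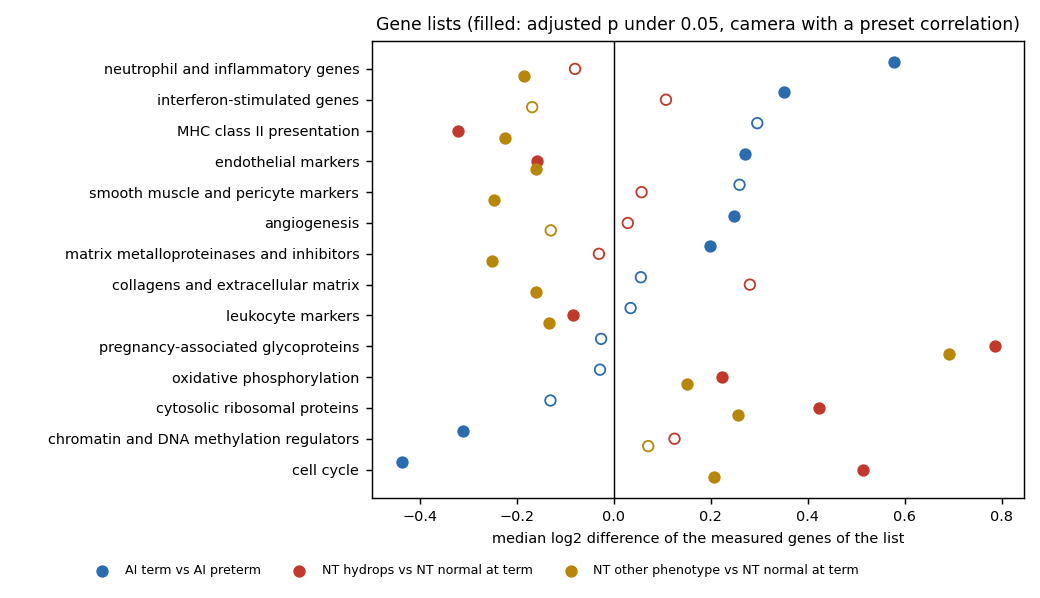
Median log2 difference of the measured genes of 14 fixed lists in 3 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation. Cytosolic ribosomal proteins, pregnancy-associated glycoproteins and cell cycle genes lie to the right of 0 in both NT comparisons, and cell cycle genes lie at −0.44 in AI term against AI preterm; no point stays filled with an estimated correlation.

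NT placentomes with hydrops and AI placentomes were compared preterm, 3 against 4. No probe of 13709 passed (limma, 803 at an unadjusted p under 0.05, and 0 in the fit of single arrays with the placentome as a random block). CYP19A1, aromatase, stood at 2.80 ± 0.85 (SD, n = 3) in hydrops and at 6.09 ± 1.12 (n = 4) in AI placentomes, with 3 of 3 below all 4 (difference −3.28, SE 0.83, adjusted p = 0.709, not passing). It was the 1 of 18 steroidogenesis genes to pass when adjusted over the list alone (adjusted over that list, p = 0.00717). DYNLRB2 (−1.51) and TCEAL8 (0.90) did not pass (adjusted p = 0.709). The list of collagens and extracellular matrix lay higher in hydrops (39 of 54 genes positive, median 0.42, camera adjusted p = 0.00751, and adjusted p = 0.575 with an estimated correlation), with 0 members past the threshold over all probes or over the list alone, for example SPARC at 1.24 and LOXL2 at 1.13. The call was lost without AI preterm placentome 29 (adjusted p = 0.292). Leaving out a placentome gave 0 lists without AI 29, 2 without AI 5, 3 without AI 15 and 5 without NT 3. With sample quality weights, 1820 probes passed, but the highest weight of all placentomes (5.58) fell on placentome 1, 1 of the 3 hydrops placentomes here.

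Within NT hydrops, term placentomes were compared with preterm ones, 3 against 3. CR2 stood at 4.79 ± 0.15 (SD, n = 3) at term and at 1.16 ± 0.74 (n = 3) preterm (difference 3.62, SE 0.58, adjusted p = 0.00578), and another CR2 probe had the same sign and did not pass. A probe with no gene listed rose by 2.16 (0.83 ± 0.27 against −1.33 ± 0.57, SE 0.34, adjusted p = 0.0049). In both, 3 of 3 term placentomes lay above all preterm ones, and both calls were lost without hydrops preterm placentome 6 (adjusted p = 0.147). These 2 were the only calls among 13696 probes (limma, 1268 at an unadjusted p under 0.05), with 44 calls in the fit of single arrays with the placentome as a random block, and no list passed. Of 18 steroidogenesis genes 0 passed over all probes, and 4 passed when adjusted over the list alone, all higher at term. These were CYP11A1 (1.56, SE 0.38, adjusted over the list p = 0.00421), the side chain cleavage enzyme that starts steroid synthesis, CYP19A1 (3.02, SE 0.89, 0.0161), HSD3B1 (1.14, 0.0427) and SULT1A1 (1.12, 0.0427). PTGS2 (3.92, SE 1.05) passed when adjusted over the list of prostaglandin and parturition genes alone (0.02). These adjustments over a list were not corrected for the number of lists. The CYP19A1 results here and against AI preterm placentomes rest on the same 3 preterm hydrops placentomes.

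The difference between hydrops and AI placentomes was also compared between term and preterm. No probe of 13645 passed this interaction (limma, 1404 at an unadjusted p under 0.05, and 20 in the fit of single arrays with the placentome as a random block). ZBTB38 (−1.33, SE 0.26), TMEM265 (1.20) and MBNL3 (1.90) had the smallest p and did not pass (adjusted p = 0.122). By camera 5 lists passed at the preset correlation and 0 with an estimated correlation. Endothelial markers lay lower (median −0.40, camera adjusted p = 0.00162, and adjusted p = 0.633 with an estimated correlation), MHC class II genes lay lower (median −0.40, 0.00718, and adjusted p = 0.388 with an estimated correlation), and cell cycle genes lay higher (median 0.67, 0.00289, and adjusted p = 0.668 with an estimated correlation). Of 10 MHC class II genes, BOLA-DRB3 (−1.77) passed when adjusted over the list alone. The cell cycle call was lost without hydrops preterm 6 (0.0569), and the weaker calls of interferon-stimulated genes (0.0224) and of neutrophil and inflammatory genes (0.0347) were lost without hydrops 6 (both 0.0569), without AI preterm 29 (0.0753 and 0.0717) and in 3 and 5 further fits that left out a placentome. Without hydrops preterm 6 only 2 lists passed, and without AI preterm 29 only 3.

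NT placentomes with hydrops were also compared with AI placentomes at term, 3 against 5. ECI2 stood at −0.24 ± 0.44 (SD, n = 3) against 2.05 ± 0.24 (n = 5) (difference −2.29, adjusted p = 0.00669), and the calsyntenin CLSTN1 at 2.91 ± 0.29 against 0.52 ± 0.84 (difference 2.39, adjusted p = 0.0121). Both lost their calls without hydrops placentome 31 (adjusted p = 0.055 and 0.116). PCSK2 (−1.48, adjusted p = 0.0153) lost its call in 3 of 8 fits that left out a placentome, ENPP1 (2.54, 0.023) in 4, GTPBP1 (2.39, 0.028) in 6 and CALCRL (−1.38, 0.0476) in 7. Of 50 cell cycle genes, 44 were positive and CCND3 (0.70) passed (median 0.58, camera adjusted p = 0.000312, and adjusted p = 0.714 with an estimated correlation). Endothelial markers lay lower with 0 of 25 genes past the threshold (median −0.23, camera adjusted p = 0.0137, and adjusted p = 0.714 with an estimated correlation), a call lost without hydrops 31 (0.0969) or AI 8856 (0.315). Of 13729 probes, 167 were higher and 38 lower (limma), 2275 had an unadjusted p under 0.05, 37 were higher and 16 lower without centring, and 157 were higher and 76 lower after quantile normalisation. With sex as a covariate 0 probes passed (limma, 576 at an unadjusted p under 0.05), and the median over the 205 called probes went from 1.10 (SE 0.25) to 0.86 (0.39). With only the compared groups 10 passed, and with the sample in Cy3 alone 0 passed (1107). Only 1 probe passed without hydrops 31, 46 without hydrops 13, 58 without hydrops 10, 56 without AI 1039, 114 without AI 9026, 118 without AI 9674, 120 without AI 1985 and 352 without AI 8856.

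NT placentomes of other phenotype were also compared with AI placentomes at term, 5 against 5. TFPI2, an inhibitor of serine proteases in the extracellular matrix, stood at −3.65 ± 0.82 (SD, n = 5) against −1.15 ± 0.95 (n = 5) (difference −2.50, adjusted p = 0.00904), with 5 of 5 below all AI placentomes. WDR5, a subunit of histone methyltransferase complexes, stood at 2.29 ± 0.63 against 0.73 ± 0.37 (difference 1.55, adjusted p = 0.0185), with 4 of 5 above. TFPI2 and WDR5 kept their calls in all 10 fits that left out a placentome, while NPY2R (−2.31, adjusted p = 0.02) lost its call in 2, CLSTN1 (1.83, 0.02) in 3, the uterine serpin SERPINA14 (−3.32, 0.0273) in 5 and SLC5A6 (1.60, 0.0443) in 7. Of 40 chromatin and DNA methylation regulators 3 rose (HMGA1 by 0.88, EHMT1 by 0.71 and EHMT2 by 0.66) and 0 fell (5 rose when adjusted over the list alone), with a camera adjusted p of 0.0328, adjusted p = 0.548 with an estimated correlation, and 0.00441 with fry. Of 41 neutrophil and inflammatory genes 3 fell (IL18 by 1.86, TLR4 by 1.31 and IL1B by 1.18; 6 when adjusted over the list alone), with a camera adjusted p of 0.0194. Cell cycle (1 of 50 rose, 0.00546), endothelial (1 of 25 fell, ACVRL1 by 1.4, 0.023) and interferon-stimulated genes (0 of 27 passed, 0.0486) also passed, and these and the neutrophil list had adjusted p = 0.759 with an estimated correlation. Without NT 14 none of the 5 lists passed (adjusted p from 0.229 to 0.306), without AI 8856 only 1 passed, without NT 32 2 and without AI 9026 3.

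Of 13712 probes compared between NT placentomes of other phenotype and AI placentomes, 259 were higher and 180 lower (limma), 2965 had an unadjusted p under 0.05, and without centring 32 were higher and 502 lower. With sex as a covariate 0 probes passed (limma, 951 at an unadjusted p under 0.05), and the median over the 439 called probes went from 0.87 (SE 0.22) to 0.77 (0.37). No probe passed with the sample in Cy3 alone (1856 unadjusted) or with only these groups in the fit (1811). With the sample in Cy5 alone 6 passed. Leaving out a placentome gave 121 calls without AI 1985, 137 without AI 1039, 149 without AI 9674, 154 without AI 9026 and 1340 without AI 8856, and 133 without NT 19, 232 without NT 32 and 1002 without NT 20.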

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

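The tests of the IVF pattern below were chosen after the result was seen, except for the count of calls without the placentomes with many missing spots, which was chosen before.

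Both IVF placentomes that entered no comparison resembled the IVF group in several of the genes by which IVF differed from NT normal and AI placentomes at term. In preterm IVF placentome 4, SLU7 stood at 3.08 where the highest NT normal or AI term placentome stood at 2.47, CCT2 at 1.07 against −0.31, ALDOC at 0.25 against −0.03 and DPYSL3 at −1.44 against −1.62. In IVF placentome 22, of other phenotype, SLU7 stood at 3.32 against 2.47, CCT2 at 1.95 against −0.31, ALDOC at 0.58 against −0.03 and EVPL at 2.61 against 2.19. These are signals in samples that no comparison used. Not every such gene did so. KPNA3 stood at 0.21 in placentome 4, where the means were 1.34 in IVF and 0.05 in NT normal term placentomes. DPYSL3 stood at −2.04 in placentome 22, where these means were −1.20 and −2.04.

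The pattern behind these values was a set of 13 probes called in the same direction in IVF against both NT normal and AI placentomes (10 higher in IVF), and 10 lay on the IVF side in unused placentome 4, 12 in placentome 22 and 9 in both, against 0 to 4 (median 1) in the other 15 NT and AI placentomes outside these comparisons. Conception by IVF predicted 80% on that side in both, which was not reached, so IVF as such stayed open and cannot be told apart from a difference in cows, sires or hybridisation between the IVF pregnancies and the others, none of which the labels give, while the sex of the calf was excluded as the whole cause, because the fewest in an unused IVF placentome were 10 (placentome 4, female calf, where the highest of 11 unused placentomes with female calves was 4) and placentome 22, with a male calf, had 12 where the highest of 4 with male calves was 3. Without the placentomes with many missing spots, none of them IVF, the number called in both fell to 8 of 13, short of the 80% set before. Against NT the other adjusted p-values (limma) rose to between 0.0589 and 0.0727, with smaller differences and a nearly unchanged median SE. By the bound set after, 11 of 13 probes kept at least 80% of their difference, beyond 2 SE, in both comparisons (lowest 77.9% against NT and 79.2% against AI). The medians were 1.51 (SE 0.27) against NT, before 1.60 (0.27), and 1.78 (0.32) against AI, before 1.89 (0.31). These values argue against such placentomes as the whole cause. They were not excluded, because the count set before did not decide and the 13 probes were chosen with them included.

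A placentome far from the others of its group was found in 8 of 185 tests, where chance alone gives about 1 in 20. XIST stood at 4.88 in NT normal placentome 2, with the nearest of its group at 3.09. KPNA3 stood at 1.10 in NT normal placentome 21 (nearest 0.32). SNCAIP stood at 3.86 in IVF placentome 36 (nearest 4.48). In NT placentome 20, of other phenotype, SLC5A6 stood at 1.78 (nearest 3.61) and WDR5 at 1.20 (nearest 2.42). Among AI term placentomes, SLU7 stood at −0.78 in 8856 (nearest 1.35), ALDOC at −1.81 in 1985 (nearest −0.84) and KCNE2 at 1.46 in 9674 (nearest 0.34).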

How the results depend on the processing

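The covariate for the 5 placentomes with many missing spots, the fits without them and the values kept at the ceiling were chosen after the data were seen. No named gene turned its direction under the alternatives that gave it a value, while the medians of the cell cycle and oxidative phosphorylation lists between other and normal NT placentomes turned to −0.01 and −0.09 under 1 scaling. Over the 94 results of named genes that passed, 1933 of 2439 alternative values stayed past the threshold with the same sign and 506 did not pass, and 903 of 1108 fits that left out a placentome kept the call. Of the 94 calls, 68 ended with the sample in Cy3 alone, 57 with sex as a covariate, 48 with only the compared groups in the fit and 45 with the sample in Cy5 alone. Of 12 genes named as not passing, 13 of 309 alternative values passed. Each array is 1 hybridisation, and the median correlation per probe between dye orientations was 0.254. The number of arrays limited the precision, and signal over background was not examined. Simulated changes of 1 on the log2 scale were recovered in 36% to 76% of probes and changes of 2 in 80% to 98%, depending on the comparison. Of the calls in that simulation 2.65% to 8.33% were false, over 5% in AI term against preterm (11 of 132) and in other NT phenotypes against AI (9 of 133). Each probe was drawn independently there, so the simulation could not show false calls from a structure shared across probes. Unless said otherwise, the cause of a change in a count was not tested. No paired analysis was possible because the replicate numbers name separate placentomes and the groups share none. Fits by orientation, of the compared groups alone, with single-sex IVF groups or without a placentome hold fewer values by construction.

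Probe counts are given as NT normal against AI (754 in the main processing), NT normal against IVF (25), IVF against AI (105), AI term against preterm (573), hydrops term against preterm (2), hydrops against AI at term (205) and other NT phenotypes against AI (439). With no centring these were 327, 54 and 64 for the first 3, 4 for hydrops term against preterm and 53 for hydrops against AI, and 1 probe passed between other and normal NT placentomes. No centring moved the median of all probes by up to 0.25 (between other and normal NT placentomes −0.25). Scaling to the same median absolute deviation gave 12 in hydrops term against preterm, 413 in hydrops against AI and 226 in other NT phenotypes against AI. Quantile normalisation gave 1 in hydrops term against preterm. The random block fit gave 91 against IVF, 305 in IVF against AI, 940 in AI term against preterm, 44 in hydrops term against preterm, 532 in hydrops against AI, 720 in other NT phenotypes against AI, 6 in hydrops against NT normal, 2 in other against normal NT placentomes and 20 in the interaction. With the sample in Cy5 alone the counts were 202 against IVF, 15 in IVF against AI, 122 in AI term against preterm, 1 in hydrops term against preterm, 110 in hydrops against AI and 6 in other NT phenotypes against AI. With Cy3 alone they were 9, 3, 13, 229, 0, 0 and 0 in the order above, where the zeros stood beside 840, 1107 and 1856 probes at an unadjusted p under 0.05 (limma). With only the compared groups they were 70, 85, 201, 90, 0, 10 and 0, with 1461 and 1811 unadjusted beside the zeros. With sex as a covariate they were 0, 0 and 55 for the first 3 and 0 in hydrops and in other NT phenotypes against AI, with 1220, 907, 576 and 951 unadjusted beside the zeros. Sex is estimated there from the 2 female and 5 male IVF placentomes alone, and in NT normal against AI the median difference of the called probes was 0.71 (median SE 0.33) beside 0.72 (0.18) without it. Female IVF placentomes alone gave 0 against NT (738 unadjusted) and male ones alone 41 against AI. The filter on dye-swap correlation gave 288, 46 and, in other NT phenotypes against AI, 224. Sample weights, from 0.214 to 5.58, gave 2003, 251, 921, 2197, 1115, 1562 and 1372 in the order above, 1820 in hydrops against AI preterm, 1 in other against normal NT placentomes and 649 in the interaction. The missing-spot covariate gave 1419, 308 in IVF against AI, 989, 6, 461 and 1210, and leaving those placentomes out gave 1987, 601, 1246, 17, 869 and 1838 in the same order, and 2 in the interaction. Single-array values and ceiling values kept moved no count by over 1.5 times.

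Gene lists past the threshold fell to 0 with an estimated correlation, with or without the missing-spot covariate, in all 9 comparisons that had any. The mean of all probes of a gene gave 1 list in NT normal against IVF. No centring gave 2 in hydrops against AI preterm and 3 in other NT phenotypes against AI. Scaling to the same median absolute deviation gave 2 in hydrops against AI preterm, and quantile normalisation gave 1 in hydrops against AI at term. The missing-spot covariate gave 1 in NT normal against IVF, 2 in IVF against AI, 0 in hydrops against AI preterm and 1 at term. Without those placentomes the lists were 2 in NT normal against AI, 1 against IVF, 2 in IVF against AI, 3 in other against normal NT placentomes, 3 in AI term against preterm, 0 in hydrops against AI preterm and 1 at term, 0 in other NT phenotypes against AI and 3 in the interaction.

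Leaving out each placentome in turn gave these lowest and highest numbers of probes and of lists. They were 142 to 1855 probes and 0 to 2 lists in NT normal against AI, 14 to 39 and 0 to 4 in NT normal against IVF, and 41 to 210 and 1 to 6 in IVF against AI. They were 0 to 0 and 7 to 7 in hydrops against NT normal, 0 to 0 and 3 to 13 in other against normal NT placentomes, and 175 to 1158 and 4 to 8 in AI term against preterm. They were 0 to 1 and 0 to 5 in hydrops against AI preterm, 0 to 3 and 0 to 1 in hydrops term against preterm, 1 to 352 and 1 to 2 in hydrops against AI at term, 121 to 1340 and 0 to 6 in other NT phenotypes against AI, and 0 to 1 and 2 to 7 in the interaction.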

Other observations

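The gene groups and samples described in this part, and the test of missing spots below, were chosen after the data were seen, while the tests of sex, of term change, of maternal tissue and of tissue identity were chosen before, and the test of failed spots after.

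AI term placentomes had the lowest group mean of LAMA5 and the highest of ECI2. LAMA5 stood at −0.07 ± 0.60 (SD, n = 5) in AI term placentomes, and the means of the other groups of at least 3 placentomes ran from 1.30 ± 0.20 (n = 4) in AI preterm to 1.67 ± 0.33 (n = 3) in NT hydrops at term. ECI2 stood at 2.05 ± 0.24 (n = 5) in AI term and at 0.62 ± 0.86 (n = 4) in AI preterm placentomes. CYP19A1 stood at 2.80 ± 0.85 (n = 3) in preterm hydrops placentomes, below the means of AI preterm (6.09 ± 1.12, n = 4), AI term (6.42 ± 1.62, n = 5), IVF term (5.76 ± 0.26, n = 7), NT normal (5.90 ± 0.99, n = 9) and NT hydrops term placentomes (5.83 ± 0.21, n = 3). PTGS2 was low in both preterm groups, at 2.02 ± 1.64 (n = 4) in AI and at 1.30 ± 1.05 (n = 3) in hydrops placentomes, and stood at 5.22 ± 1.17 (n = 3) in hydrops placentomes at term. OXTR stood at 0.42 ± 0.44 (n = 4) and 0.34 ± 0.29 (n = 3) in these preterm groups and at 1.09 ± 0.64 (n = 3) in hydrops placentomes at term. In IVF preterm placentome 4, PTGS2 stood at 1.15.

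The differences between term and preterm placentomes were set side by side in AI and in hydrops pregnancies. Across 13645 probes, which are not independent replicates, the term minus preterm differences of the pair correlated at 0.208. Of 570 probes called in AI, 378 (66.3%) had the same sign in hydrops, with a median of 0.18 in the direction of the AI call beside a median size of 1.11 in AI. Of the 20 signed regroupings of the 6 hydrops placentomes, 3 gave a median as high, so the shared direction was not beyond chance. Comparisons that share a group also share its chance values. NT normal and IVF placentomes against the same AI placentomes had 35 higher and 9 lower calls in common, where independent lists would share 2.59 and 0.618, and their differences correlated at 0.67 where unchanged groups gave 0.616 (covariance 0.109 against 0.0534). With the AI placentomes split between the comparisons the median correlation was 0.212 (0.0607 to 0.42). Hydrops and other NT phenotypes against AI had 98 higher and 16 lower calls in common, where independent lists would share 3.14 and 0.5, and correlated at 0.757 where unchanged groups gave 0.442 (covariance 0.184 against 0.0535), and at a median of 0.418 (0.21 to 0.581) with the AI placentomes split. Hydrops and other phenotypes against NT normal had 0 calls, and their differences correlated at 0.469 where unchanged groups gave 0.304 (covariance 0.0515 against 0.0299), and at a median of 0.177 (−0.0856 to 0.251) with the NT normal placentomes split.

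For the 754 probes called between NT normal and AI placentomes at term, the sex of the calf was tested in IVF placentomes. Over these probes their female minus male difference, signed by the call, had a median of 0.00139 (−0.0795 to 0.0839 with each IVF placentome left out). The median called difference was 0.72. These values argue against sex as the whole cause, provided that sex acts in IVF placentomes as in the others. The test rests on 2 female and 5 male IVF placentomes. In NT and AI placentomes sex follows the group, so the design cannot exclude it there, and sex stays open for single genes. Placentomes with many missing spots were excluded, because 753 of the 754 probes (99.9%) still passed with these placentomes as a covariate. A less advanced term change in NT placentomes stayed open. The median term minus preterm difference of hydrops placentomes, signed by the call, was 0.163. Of 20 signed regroupings, 2 gave a median as high, counting the real one, and the highest was 0.19. A median of 0 or above was a wrong bound for excluding this explanation, since these placentomes hardly showed the term change of AI placentomes (0.18 beside 1.11, as above). Cloning itself was not tested apart from these, and the cows, sires and hybridisation dates behind the groups were not given. Each comparison with 105 or more calls held the AI term group, and those without it gave 25 or fewer. In the labels the AI term placentomes are numbered from 1039 to 9674 and all others from 1 to 46. Whether this group was collected apart is not given. The calls of NT against AI at term therefore cannot be told apart from a feature of the AI term group. Taken alone, the calls of IVF against AI and of AI term against preterm share this limit.

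XIST lay far below the reference in IVF placentome 22, of other phenotype and with a male calf, at −5.32 (−3.87 and −6.78 on its arrays), where the other 14 male calves gave 2.41 ± 1.10 (SD). Failed spots stayed open, since 3 of 3 measured spots lay below the reference (highest −2.87), which the array values made all but certain, and 1 array gave a single spot. Another tissue than placentome was excluded, since its median correlation with the other term placentomes was 0.809, above the lower quartile of 0.785, and 10 of 29 term placentomes had a lower one. Little maternal tissue in this sample cannot be told apart from other sources, since its mean over the maternal caruncle and endometrium list was 0.614, below the quartiles of the other placentomes (0.66 to 0.853), and 6 of 37 had a lower mean. No biological explanation was tested for this value.

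Other splits of the same placentomes into groups of the same sizes were refitted, 100 where there were more, and each number of splits as large counts the real split. For the count of probes, no other split was as large in some comparisons, a share under 0.05. These were NT normal against AI (1 of 100 splits as large, real 754, highest other 636) and NT normal against IVF (1 of 100, 25, highest other 1). IVF against AI (1 of 100, 105, highest other 1) and hydrops against AI at term (1 of 56, 205, highest other 13) were the others. The split with 636 calls put all 3 placentomes with many missing spots in the smaller group. A share under 0.05 was also reached for AI term against preterm (3 of 100, real 573) and for other NT phenotypes against AI (3 of 100, real 439). There the highest other splits, with 938 and 1783 calls, put both placentomes with many missing spots in 1 group. With the covariate for these placentomes the real splits gave 989 and 1210. None of the shares was adjusted for the 11 comparisons, and 1 of 100 or 1 of 56 was the smallest share these splits could give. With that number of comparisons chance was therefore not excluded for any of these counts. Where 0 probes passed every split is as large by construction, so the splits decide nothing for hydrops against NT normal (100 of 100, highest other 349, with both such placentomes in the group of 3), other against normal NT placentomes (100 of 100, highest other 5), hydrops against AI preterm (35 of 35, highest other 8) or the interaction (100 of 100, highest other 28). The splits with 349 and 1783 calls point to a structure of the samples, whose cause was not tested. For hydrops term against preterm the 10 splits are too few for a share under 0.05 (real 2, highest other 1, with 1 split as large).

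For the count of gene lists, a share under 0.05 was reached only for other against normal NT placentomes (2 of 100 splits as large, real 11, highest other 11). That count rested on NT placentome 14, without which 3 lists passed. The share was not adjusted for the 11 comparisons, and another split gave as many lists. Chance was therefore not excluded for this count. It cannot be excluded for NT normal against AI (86 of 100, real 1, highest other 11), IVF against AI (93 of 100, 1 and 12), hydrops against NT normal (12 of 100, 7 and 10), AI term against preterm (19 of 100, 7 and 11), hydrops against AI preterm (24 of 35, 1 and 5), hydrops against AI at term (46 of 56, 2 and 9), other NT phenotypes against AI (41 of 100, 5 and 12) or the interaction (11 of 100, 5 and 10). For NT normal against IVF, with 0 lists, every split is as large by construction (100 of 100, highest other 10). For hydrops term against preterm the 10 splits are too few (10 as large, real 0, highest other 2).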
